A study of Drosophila melanogaster with 6 samples.

How the data were processed

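RNA-seq values of wandering larval brains were used from 6 samples of 3 groups (control, activation and ablation, 2 samples each). Each sample is a pool of 86 to 100 brains from larvae reared at 25 °C on food with 35 g yeast per liter. Per the submitters' processing notes, reads were processed with TopHat2, Cufflinks and Cuffdiff on genome build dm3. Their versions, options and annotation are not given in the sources used here. The authors deposited 3 Cuffdiff tables, for control against ablation, control against activation and activation against ablation, with 21081 transcripts each. The tables name the activation group induction. The values are FPKM (fragments scaled to transcript length and library size), 1 per group, scaled by the authors within each table. The log2 fold change is the authors' log2 ratio of the group values, infinite where a group is 0. The test statistic is a score deposited with tested transcripts that have no group at 0, and the deposited p-value and q-value come from Cuffdiff's test over both samples of a group. The smallest deposited p-value is 5e-05. The q-values were recomputed as Benjamini-Hochberg values over the transcripts with test status OK and differed by at most 5.15e-07. Control values differed 1.03 times between the tables as a median, activation values 0.993 times and ablation values 1.01 times, so each comparison uses its own table. Sequencing depth and values per replicate are not in these tables, so no count interval, no replicate spread and no outlier test could be given.

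Transcripts were matched to genes by their CG number. Of 14012 genes 12914 were named from the reference annotation by locus tag and 171 by synonym, and 927 kept their CG number alone. The reference annotation is of another build than dm3, so it was used for names only, and coordinates (dm3, counted from 1) are those of the loci in the deposited tables. Gene sums add the FPKM of all transcripts of a gene, and 10456 genes have 1 transcript.

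Calls are transcripts with status OK and a deposited q of at most 0.05. A fold change of a gene list is the median of log2((FPKM + 1)/(FPKM + 1)) over the gene sums of its tested genes, set against 10000 random lists of tested genes of the same size drawn from 10 expression bins. A list is outside the random range when it lies beyond the middle 95% of them. Percentiles describe these libraries and are no p-values across samples. Called members were also counted with the deposited p-values adjusted over the list alone by Benjamini-Hochberg. The 33 lists hold 995 entries, of which 974 were found. They cover brain cell types, neuronal signalling, hormones, metabolism, stress and immunity, and markers of gut, fat body, salivary gland, muscle, haemocytes, cuticle and discs. After the data were seen, 3 entries that matched a gene other than the one meant were left out.

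Named transcripts follow a rule: the design genes shi, w, y and para, the 8 called transcripts with the largest rise and the 8 with the largest fall of log2((FPKM + 1)/(FPKM + 1)) in each comparison, and up to 4 called members of each list. Any other transcript named was chosen after its values were seen. The groups, comparisons, lists, naming rule and most alternative settings were fixed before the data were examined.

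Overlap and correlation of the control comparisons were set beside 100 simulations of unchanged groups with a shared control, with standard errors taken as the log2 fold change over the deposited statistic. Called genes per chromosome arm were tested with Fisher's exact test, two-sided, adjusted over 6 arms, and neighbours with 10000 shuffles within arms. The adjustment and the list method were run on simulated normal scores in which 200 transcripts were given a large shift. They recovered 99%, 100% and 99.5% of these in the 3 comparisons, placed 100 of 100 shifted lists outside the random range, and placed 4%, 6% and 6% of unshifted lists outside it. Cuffdiff's test, its smallest p-value and groups at 0 were not simulated. The recovery therefore checks the computation and does not give the share of real changes that the calls would find. Alternatives were other q thresholds, a minimum of 1 FPKM, a minimum change of 1.5-fold, centring on the median, normal p-values from the statistic, adjustment over all 3 tables together, and pseudocounts of 0.1 and 5. Settings that need values per replicate could not be run. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.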

Results

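RNA from pooled brains of wandering Drosophila melanogaster larvae was sequenced in 6 samples, 2 in each of 3 groups. All larvae carried E347-GAL4, a driver line that switches on UAS transgenes in the neurons the series calls E347 neurons. Control larvae carried the driver in a cross to w1118, and their pools held 100 and 86 brains. Activation larvae also carried UAS-NachBac on the third chromosome, and their pools held 100 and 97 brains. NachBac is a bacterial voltage-gated sodium channel that makes neurons more excitable. Ablation larvae carried UAS-ShiDN, a dominant-negative form of shibire, the fly dynamin, on the X and the second chromosome, and their pools held 100 and 91 brains. The series describes this last group as neuronal ablation. The values used here are the authors' group values in FPKM for 21081 transcripts of 14012 genes, 1 value per group in each of 3 tables. They carry no value per replicate, so no spread between replicates stands beside a value, and the sequencing depth of each sample is unknown. In the table of control and ablation, 8186 genes reached 1 FPKM in control and 8637 in ablation. In the table of control and activation, 8633 genes reached 1 FPKM in activation.

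The comparison of control with ablation asks which brain transcripts differ when E347 neurons express dominant-negative shibire. Some of the transcripts listed at 0 in control and present in ablation encode secreted or digestive proteins. Jon74E, a Jonah family serine protease of the midgut, had an authors' group value of 38.6 FPKM in ablation, PGRP-SC2, a secreted peptidoglycan recognition protein, had 23.4 FPKM, and Phae2, a serine protease, had 14.9 FPKM. Transcripts listed at 0 in ablation included Cib2, a calcium and integrin binding protein, at 15.1 FPKM in control, topi, a zinc finger gene of spermatocyte transcription, at 5.41 FPKM, and Sb, a membrane serine protease of imaginal disc shaping, at 3.50 FPKM. Cpr49Ac, a cuticle protein, fell from 14.8 FPKM in control to 0.000654 FPKM in ablation by its RA transcript, while the sum over its 2 transcripts was 14.8 FPKM and 3.77 FPKM.

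In the authors' deposited table, 18 of 11676 tested transcripts passed at q of at most 0.05, 10 higher and 8 lower in ablation. Each of the 18 had p = 5e-05 and q = 0.0324 in the authors' deposited table. Of these transcripts 17 were listed at 0 in control or in ablation, and Cpr49Ac was the 1 with values above 0 in both groups. The other rises by the naming rule were CG31789 at 160 FPKM in ablation, CG13324 at 34.7 FPKM, CG17145 at 22.5 FPKM and Ag5r2, an antigen 5 related protein, at 16.8 FPKM. The other falls were CG12857 at 11.9 FPKM in control, CG31231 at 6.90 FPKM and yellow-e, a member of the yellow family, at 5.74 FPKM. For Cpr49Ac, for Jupiter, which encodes a microtubule-associated protein, and for RpS3A, a ribosomal protein gene, the call rested on 1 of several transcripts. Jupiter RH was listed at 0 in control and 280 FPKM in ablation, while the sum over all Jupiter transcripts was 845 FPKM in control and 662 FPKM in ablation. RpS3A RB was at 442 FPKM in control and listed at 0 in ablation, while the sum over all RpS3A transcripts was 2696 FPKM in control and 4068 FPKM in ablation. In dm3, Jon74E lies on 3L from 17539968 to 17542143, PGRP-SC2 on 2R from 4604472 to 4605026, Phae2 on 2L from 12111124 to 12111945, and Cib2 on 2R from 16767554 to 16769910. The smallest p in the authors' deposited table was 5e-05, and 12 transcripts at that p are needed before any passes, so the count moves in steps. With normal p-values from the deposited statistic, which is missing wherever a group is at 0, 10 transcripts passed, none of them among the 18.

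The midgut digestive enzyme list stood far above random lists in ablation against control. All 14 of its tested genes had higher values in ablation, with a median log2 change of 4.89 (6.80 and 2.79 with pseudocounts of 0.1 and 5), while the middle 95% of matched random lists ran from -0.22 to 0.60. Testing depends on expression in either group, which partly sets this count and median. Of the 20 untested genes 11 were higher in ablation, 0 lower and 9 equal, and the 6 genes with at least 1 FPKM in control were all higher. Of its 14 tested transcripts 1 passed, Jon74E, and 3 passed as higher when adjusted over the list alone. Jon65Aiv, another Jonah protease, had 2.07 FPKM in control and 405 FPKM in ablation, and LysD, a lysozyme of the gut, had 2.22 FPKM and 444 FPKM, but neither passed. In control 0 of the 34 genes of this list reached 10 FPKM. The fat body list had higher values in ablation for 9 of 11 tested genes, with a median of 0.99 and a random range from -0.34 to 0.43. Cuffdiff called 0 of its transcripts, 5 had an unadjusted p under 0.05, and 3 passed as higher when adjusted over the list alone. Lsp1gamma, a larval serum protein made by the fat body, had 20.8 FPKM in control and 87.1 FPKM in ablation.

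Detoxification genes, which encode cytochromes P450 and conjugating enzymes, had higher values in ablation for 21 of 28 tested genes, with a median log2 change of 0.82 and a random range from 0.01 to 0.76. Cuffdiff called 0 of them, 4 transcripts had an unadjusted p under 0.05, and 3 passed as higher when adjusted over the list alone. With a pseudocount of 5 the detoxification list (median 0.35) and the salivary gland list (median -0.23) no longer lay outside their ranges in this comparison. Cyp6g1, a P450 of insecticide resistance, was listed at 0 in control and 2.40 FPKM in ablation. Neuropeptide genes had a median of 0.35, with 25 of 35 higher, and glycolysis genes had a median of 0.35, with 19 of 22 higher, both above their random ranges. Cuffdiff called 0 transcripts in either list, and 0 and 1 had an unadjusted p under 0.05. The cuticle and trachea list lay below its random range with a median of -0.28 and 9 of 14 genes lower, as did salivary gland markers with -0.37 and 4 of 8 lower, and muscle markers with -0.24 and 9 of 17 lower, so the last 2 lists were split nearly evenly. Of all 27 muscle genes, tested or not, 14 were higher and 12 lower, and of all 42 cuticle and trachea genes 12 were higher, 14 lower and 16 equal. Cuffdiff called 0 transcripts in these 3 lists, with 4, 0 and 0 at an unadjusted p under 0.05, and 3 cuticle transcripts passed as lower when adjusted over the list alone. Lcp1, a larval cuticle protein, had 729 FPKM in control and 156 FPKM in ablation. Of the 33 fixed lists 8 lay outside the random range, where independent lists of random genes would give 1.65. The lists share members and each group has 1 value, so this count is no test. The median log2 change over all transcripts with at least 1 FPKM was 0.15 in ablation and 0.17 in activation against control. Relative to it, medians of lists outside the random range keep their sign, here and for activation. The activity-regulated median in activation, 0.04, lies below this centre and does not. PGRP-SC2 was the 1 called transcript of the antimicrobial list, which lay within its range. Of the 18 transcripts only Jon74E stands in a list of another tissue, so 17 were left without these lists. This does not show that the 17 come from brain tissue.

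The genes that the genotypes touch did not pass in this comparison. The sum over shi transcripts, which encode dynamin, was 69.5 FPKM in control and 74.4 FPKM in ablation. White, the eye pigment transporter gene w, had 3.55 FPKM and 2.83 FPKM. The sum over para transcripts, the voltage-gated sodium channel gene of the fly, was 2.08 FPKM and 4.35 FPKM. Yellow, the pigment gene y, stayed under 1 FPKM in every group and was not tested.

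The comparison of control with activation asks which brain transcripts differ when E347 neurons express the sodium channel. Here no transcript passed, and the values that follow belong to transcripts chosen after their values were seen. Arc1, an activity-regulated gene that encodes a capsid-forming protein, had 42.9 FPKM in control and 105 FPKM in activation (p = 0.00125 and q = 0.640 in the authors' deposited table). RpL18, a ribosomal protein gene, had 1051 FPKM and 3036 FPKM, and the noncoding lncRNA:CR34335 had 2234 FPKM and 9877 FPKM. The larval cuticle genes Lcp1 and Lcp4 had 709 FPKM and 365 FPKM in control and 120 FPKM and 47.8 FPKM in activation. Arc1 does not stand for the activity-regulated list, which lay within its random range. That list had a median log2 change of 0.04, with 9 of 15 genes higher and 6 lower in activation.

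Cuffdiff called 0 of 11809 tested transcripts in this comparison, and 360 had an unadjusted p under 0.05 in the authors' deposited table, 217 higher and 143 lower in activation. These were 3.05% of the tested transcripts, with 2.05% in control against ablation and 3.21% in activation against ablation. Evenly spread p-values would give more under 0.05 in each comparison. The 11 transcripts at the smallest p of 5e-05 had q = 0.0537 in the authors' deposited table and passed at q of at most 0.1. They included RpL18, lncRNA:CR34335, CG15353 at 2489 FPKM in control and 595 FPKM in activation, and Ca-alpha1D RD, a transcript of an L-type calcium channel gene, at 0.0001 FPKM and 2.12 FPKM, with gene sums of 1.70 FPKM and 2.13 FPKM. CG32198 RB at 124 FPKM, CG11300 at 84.2 FPKM and CG13560 at 44.8 FPKM in activation were listed at 0 in control. RpS3A RB at 430 FPKM, CG14820 at 8.75 FPKM, Eig71Ee, an ecdysone-induced salivary gland gene, at 7.88 FPKM and topi at 5.25 FPKM in control were listed at 0 in activation, though the RpS3A sum was 2629 FPKM in control and 4080 FPKM in activation. In dm3, RpL18 lies on 3L from 7231642 to 7234449, CG15353 on 2L from 2006754 to 2007193 and lncRNA:CR34335 on X from 3439875 to 3440160. With 12 transcripts at the smallest p in place of 11, q would have passed, so the 0 here and the 18 in ablation do not show that the manipulations differ.

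Of the 33 lists 5 lay outside the random range in activation against control, where independent lists of random genes would give 1.65. Detoxification genes lay above it, with a median log2 change of 0.91 and 18 of 25 tested genes higher. Fat body markers lay below it, with a median of -0.98 and 8 of 10 genes lower. Lsp2, a larval serum protein, had 32.2 FPKM in control and 6.11 FPKM in activation, and Fbp1, the fat body receptor of these proteins, had 16.8 FPKM and 3.65 FPKM. Midgut markers had a median of -1.60 (-3.89 and -0.51 with pseudocounts of 0.1 and 5) over 4 tested genes, all lower, but of the 30 untested genes 11 were higher, 4 lower and 15 equal. Muscle markers had a median of -0.62, with 12 of 18 lower, and haemocyte markers a median of -0.30, with 10 of 18 lower, but of all 27 haemocyte genes, tested or not, 15 were higher and 11 lower. Cuffdiff called 0 transcripts of these 5 lists, and 0 detoxification, 4 fat body, 2 midgut, 0 muscle and 0 haemocyte transcripts had an unadjusted p under 0.05. Adjusted over the list alone, 0 transcripts of these 5 lists passed. Within their random ranges, the activity-regulated list had 1 transcript higher when adjusted over the list alone, Arc1, the ion channel list had 1, Ca-alpha1D RD, and the glia list had 2, Mdr65 and htl. Mdr65, a transporter of the blood-brain barrier, had 28.9 FPKM in control and 69.2 FPKM in activation. In the same way 2 cuticle transcripts and 1 salivary gland transcript passed as lower when adjusted over the list alone.

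White was at 3.45 FPKM in control and 25.9 FPKM in activation and did not pass (p = 0.0277 and q = 0.915 in the authors' deposited table). The shi sum was 67.7 FPKM in control and 74.0 FPKM in activation, and the para sum was 2.03 FPKM and 2.90 FPKM. No transcript of shi or para passed.

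The comparison of activation with ablation sets the 2 manipulations directly against each other. Gut lysozymes and digestive enzymes were higher in ablation: LysD and LysB, listed at 0 in activation, reached 436 FPKM and 306 FPKM, and the trypsin genes epsilonTry and betaTry, also listed at 0, reached 22.3 FPKM and 11.4 FPKM. Of 12 tested transcripts of the fat body list 5 passed as higher in ablation. Among them were the larval serum protein genes Lsp1alpha, from 5.10 FPKM to 54.5 FPKM, Lsp2, from 6.13 FPKM to 62.7 FPKM, and Lsp1beta, from 8.74 FPKM to 71.3 FPKM. Fbp1, the receptor of these storage proteins, rose from 3.67 FPKM to 48.5 FPKM. Arc1, the activity-regulated capsid gene, fell from 106 FPKM in activation to 38.9 FPKM in ablation. White, the eye pigment transporter gene, was at 26.03 FPKM in activation and 2.79 FPKM in ablation. The genotypes touch this gene, and whether its difference reflects the crosses or the manipulations was not tested.

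In the authors' deposited table, 46 of 12419 tested transcripts passed at q of at most 0.05, 31 higher and 15 lower in ablation. The log2 change in the authors' deposited table was 3.72 for Fbp1, 3.42 for Lsp1alpha, 3.35 for Lsp2, 3.03 for Lsp1beta, -1.44 for Arc1 and -3.22 for white, each with q = 0.0163. Of the 46 transcripts 38 were listed at 0 in activation or in ablation. The other rises by the naming rule, all from 0 in activation, were CG31789 at 157 FPKM, Acbp4, an acyl-CoA binding protein, at 131 FPKM, CG13323 at 74.9 FPKM, CG14036 at 48.1 FPKM, CG16713 at 24.2 FPKM and PGRP-SC2 at 22.9 FPKM. The other falls, all to 0 in ablation, were 14-3-3zeta RH, a transcript of a signalling adaptor gene, at 59.8 FPKM in activation, CG34278 at 32.9 FPKM, CG13036 at 12.4 FPKM, Cib2 at 7.97 FPKM, CG32318 at 6.64 FPKM, Gr47b, a gustatory receptor, at 2.43 FPKM, and CG12857 at 2.05 FPKM. The q in the authors' deposited table was 0.0289 for CG32318 and 0.0163 for the other transcripts named here. The sum over all 14-3-3zeta transcripts was 892 FPKM in activation and 937 FPKM in ablation, and no transcript of shi or para passed. In dm3, LysD lies on 3L from 1210485 to 1211196, LysB on 3L from 1207371 to 1207868, Fbp1 on 3L from 14087686 to 14091156, Arc1 on 2R from 10245428 to 10247799 and white on X from 2684632 to 2690499. With normal p-values from the deposited statistic, 28 transcripts passed, 7 of them among the 46.

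The midgut list had 14 of 14 tested genes higher in ablation than in activation, with a median log2 change of 4.44 (6.44 and 2.65 with pseudocounts of 0.1 and 5) and a random range from -0.24 to 0.23. Of the 20 untested genes 8 were higher, 4 lower and 8 equal. Of its 14 tested transcripts 6 passed as higher, and 10 did when adjusted over the list alone. The fat body list had 10 of 12 genes higher, with a median of 2.36 and a random range from -0.19 to 0.19. Of its 12 tested transcripts 5 passed as higher, and 7 did when adjusted over the list alone. Muscle markers had a median of 0.67, with 17 of 18 genes higher and 0 called by Cuffdiff, and 3 transcripts at an unadjusted p under 0.05. Act57B, a larval muscle actin, had 16.3 FPKM in activation and 39.1 FPKM in ablation.

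Antimicrobial and immune genes had lower values in ablation for 15 of 17 tested genes, with a median of -1.36 (-0.48 with a pseudocount of 5) and a random range from -0.32 to 0.33. Of the 25 untested genes of this list 7 were higher, 6 lower and 12 equal. In this list 1 transcript passed, PGRP-SC2, which was higher, and when adjusted over the list alone 1 was higher and 3 were lower. Drsl5, a drosomycin-like peptide, and AttB, an attacin, had 9.16 FPKM and 1.97 FPKM in activation and were listed at 0 in ablation, without passing. Heat shock and stress genes had lower values for 24 of 30 genes, with a median of -0.42 and 0 called by Cuffdiff, and 3 transcripts at an unadjusted p under 0.05. DnaJ-1, a co-chaperone, had 421 FPKM in activation and 252 FPKM in ablation. The activity-regulated list had a median of -0.22, with 10 of 15 genes lower, and Arc1 was its 1 called transcript, also when adjusted over the list alone. Insulin signalling genes had a median of -0.20, with 15 of 24 lower, 0 called by Cuffdiff and 3 transcripts at an unadjusted p under 0.05. Ilp5, an insulin-like peptide of brain neurosecretory cells, had 299 FPKM in activation and 124 FPKM in ablation, without passing. Ilp2 had 298 FPKM in activation and 293 FPKM in ablation, and Ilp3 had 69.4 FPKM and 52.7 FPKM.

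Also above the random range of this comparison lay neurotransmitter synthesis with 0.30, glycolysis with 0.29, ion channels with 0.28, neuropeptides with 0.13 and mitochondrial respiration with 0.07. Below it lay salivary gland markers with -0.65, mushroom body and optic lobe genes with -0.18, apoptosis genes with -0.15, ecdysone response genes with -0.14 and glia with -0.12. The ecdysone response list held 1 called transcript, Fbp1, which it shares with the fat body list. Cuffdiff called 0 transcripts in the other 9, with 1, 3, 2, 1, 1, 0, 1, 1 and 3 at an unadjusted p under 0.05 in that order. Mitochondrial respiration no longer lay outside with a pseudocount of 5. In all, 17 of 33 lists lay outside, where independent lists of random genes would give 1.65. Since the lists share members and each group has 1 value, this count is no test either.

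**Figure D1:**
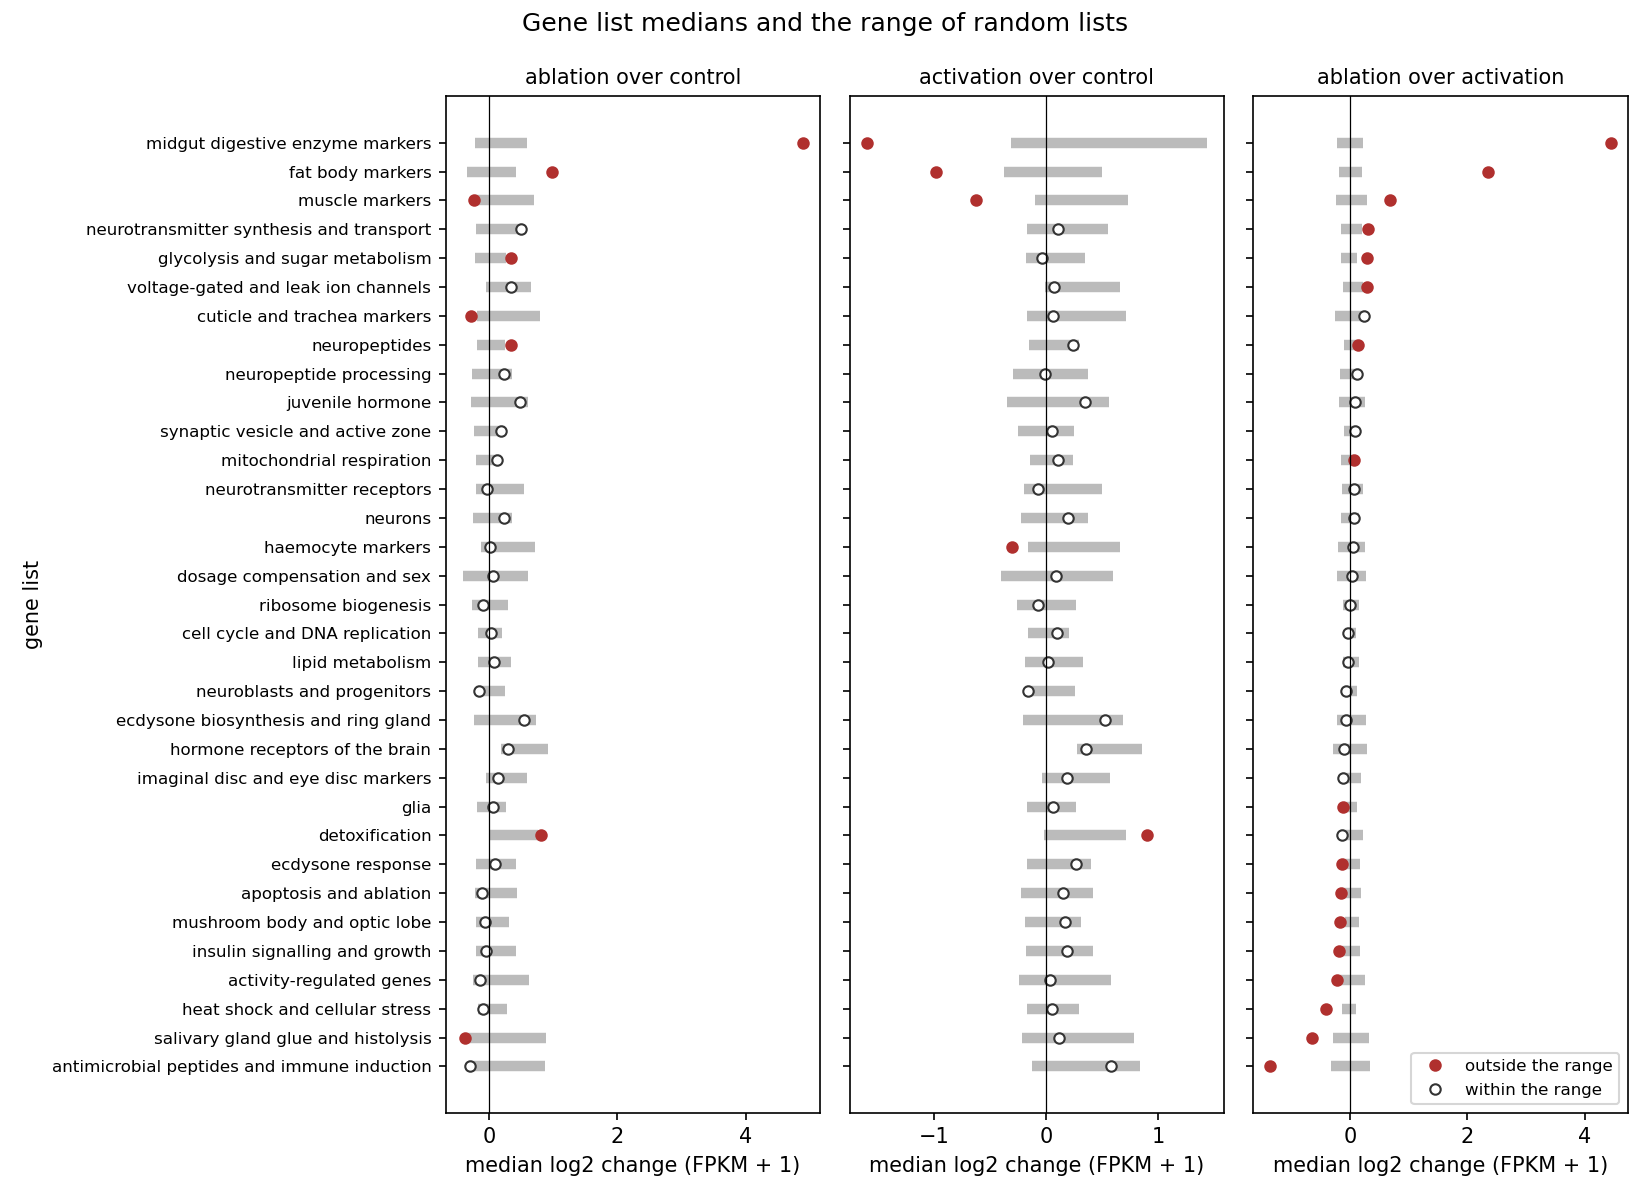
Median log2 change of FPKM + 1 for each of 33 gene lists (points) in 3 comparisons, with the middle 95% of 10000 matched random lists as grey bars. The horizontal scales differ between panels, filled points lie outside the bar, and the midgut list is at 4.89, -1.60 and 4.44 from left to right.

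**Figure D2:**
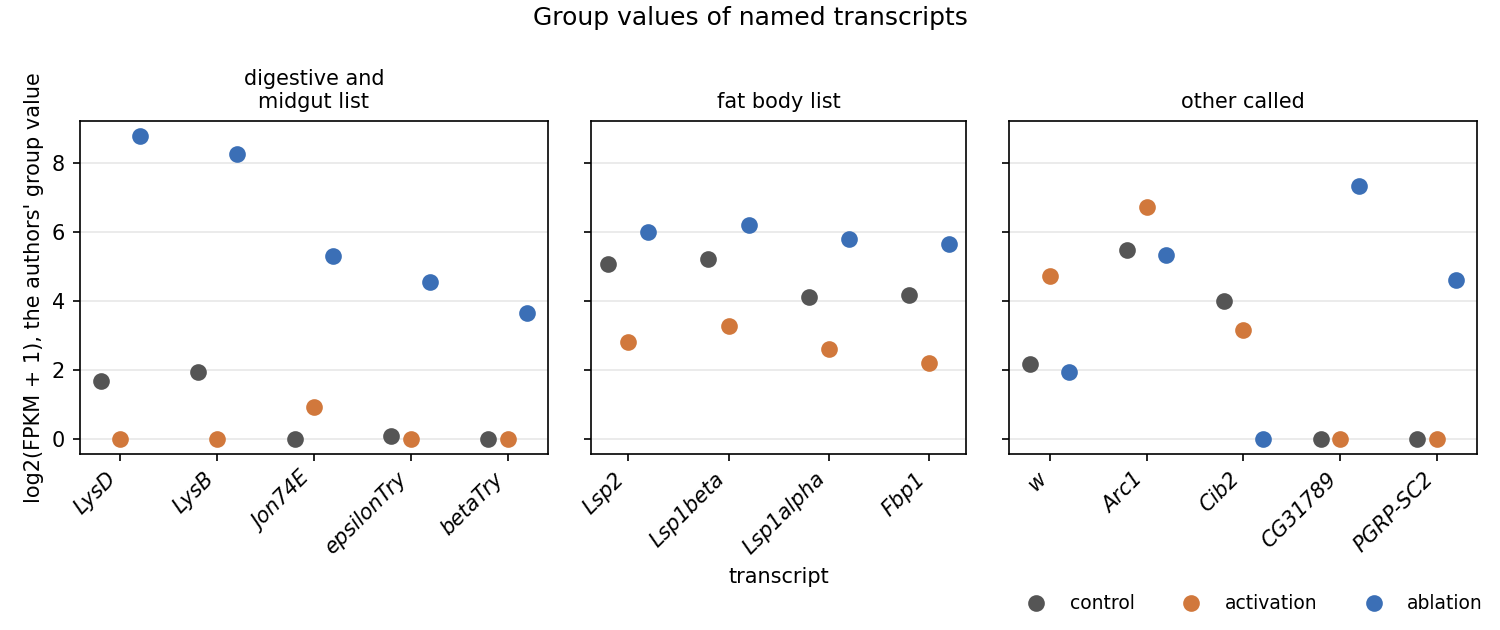
Authors' group values, as log2 of FPKM + 1, of named transcripts in control, activation and ablation brains, without error bars because the tables give 1 value per group. Control and ablation values come from the table that compares them and activation values from the table of control and activation, so that Lsp2 is at 33.0, 6.11 and 63.9 FPKM in control, activation and ablation.

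Set against control, 23 of the 46 transcripts lay on opposite sides in the 2 manipulations. The 46 were called for a difference between the manipulations, which tends to place control between them. Of the rises 25 were at 0 in activation, where any value above 0 in control counts as lower in activation. The count of 23 therefore does not show opposite effects. Of the 46 transcripts 6 had also passed in control against ablation, and 21 of the 31 rises had at most 1 FPKM in control. The larval serum proteins stood on both sides of control, as with Lsp2 at 33.0 FPKM in control, 6.11 FPKM in activation and 63.9 FPKM in ablation. None of their transcripts passed in either comparison with control. LysB and LysD were at 2.85 FPKM and 2.22 FPKM in control. Arc1 was at 44.1 FPKM in control and 39.5 FPKM in ablation.

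The last comparisons ask which transcripts moved alike in both manipulations against the control libraries that they share. At q of at most 0.05 Cuffdiff called 0 of 11030 transcripts in both, and at an unadjusted p under 0.05 there were 69, of which 41 were higher in both, 26 lower in both and 2 opposite. Independent lists would share 0.966 higher and 1.11 lower. At q of at most 0.1 there were 2, RpS3A RB and topi, both lower in both manipulations. Among 9215 transcripts with at least 1 FPKM in all groups, 39 moved the same way at an unadjusted p under 0.05. Simulations of 3 unchanged groups with the deposited errors and a shared control gave 200 on average, with a range from 175 to 237. These errors exceed the observed spread, with a median absolute deviation of log2 changes in ablation of 0.702 simulated and 0.487 observed, so the simulation does not show how many the shared control alone would give. With 0 transcripts called in control against activation, none could be called in both comparisons, in the same or in opposite directions.

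Across these 11030 transcripts, which are not independent replicates, the log2 changes in activation and in ablation had a Pearson r of 0.750, a Spearman rho of 0.766 and a covariance of 1.19, and 82.3% had the same sign. Mdr65 had 29.7 FPKM in control and 65.3 FPKM in ablation, beside its 69.2 FPKM in activation, and Lcp1 was lower in both. Among 6964 transcripts with a standard error of at most 2, r was 0.810 and rho 0.832, and the simulation without any change gave 0.792 and 0.764. The covariance in this set was 0.390 against 0.762 in the simulation, whose spread was again wider than observed, with a median absolute deviation of 0.576 against 0.427. The simulation therefore does not size the part of the correlation that comes from the shared control libraries, and with 2 of them and no value per replicate they could not be split between the comparisons.

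**Figure D3:**
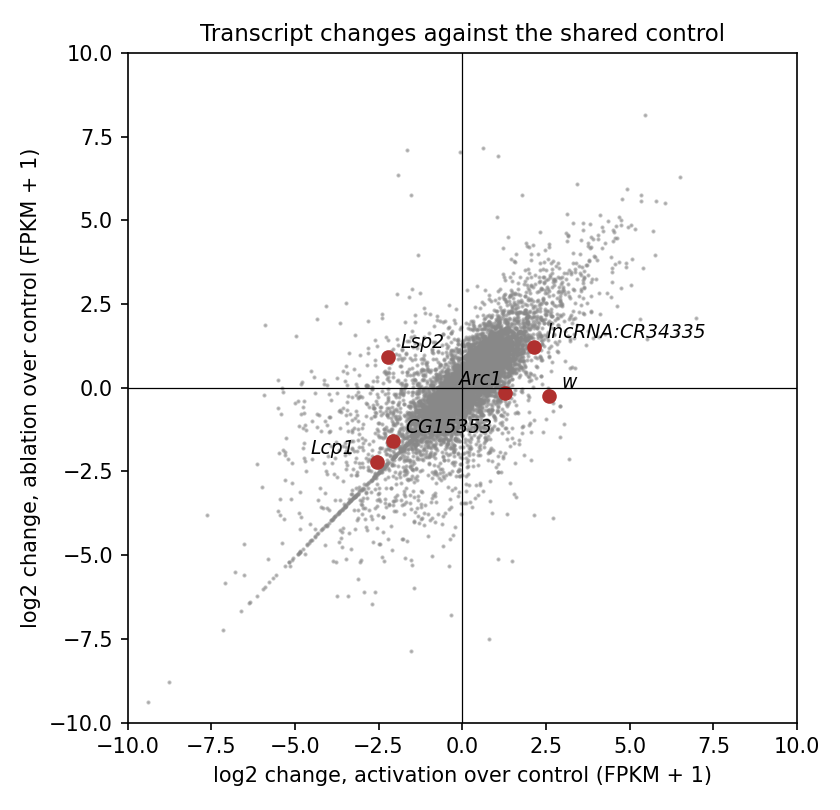
Log2 change of FPKM + 1 in activation over control (horizontal) and in ablation over control (vertical) for transcripts tested in both and with at least 1 FPKM in some group, with a Pearson r of 0.750. Red points mark named transcripts, of which Lsp2 lies on opposite sides of 0 and Lcp1 below 0 in both, and the thin diagonal line at lower left holds transcripts listed at or near 0 in both manipulations.

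Since the crosses bring in different chromosomes, the called genes were also counted by chromosome arm. In activation against ablation, 2 of 2156 tested genes on 3R were called, CG34278 and CG6295, with an odds ratio of 0.141 against the other arms (Fisher's exact test, two-sided, p = 0.000752, adjusted p = 0.00451 over 6 arms). The other arms did not pass in this comparison, with 5 genes on X, 13 on 2L, 14 on 2R, 12 on 3L and 0 on 4. In control against ablation no arm passed, and the 18 genes lay with 1 on X, 2 on 2L, 5 on 2R, 4 on 3L, 5 on 3R and 1, RpS3A, on 4. In activation against ablation, 6 pairs of neighbouring tested genes were both called, where shuffles within arms gave 0.293 on average. These were LysB with LysD, alphaTry with epsilonTry, epsilonTry with betaTry, Phae1 with Phae2, Acbp4 with Acbp6, and CG16713 with IM33, most of them members of 1 gene family each. All of these pairs lay on 2L, 2R or 3L. Fisher's exact test takes called genes as independent, which such neighbours are not, so the result for 3R does not show an effect of the crosses. The share of 10000 shuffles with as many pairs was 0.0001, the smallest they can give. In control against ablation 0 pairs were neighbours, and in control against activation no gene was called by Cuffdiff.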

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

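The tests of a lower share of brain tissue, differing fat body amounts, older larvae and larger control errors were chosen after the results were seen, and the test of brain share was rewritten after that, with an earlier form leaving it open for fat body. The direct contrast tests whether the change against control differs between activation and ablation, and it called 46 transcripts. As log2 of FPKM + 1, ablation over activation, the transcripts named by rule that were higher in ablation differed by 8.77 for LysD, 8.26 for LysB, 7.31 for CG31789, 7.05 for Acbp4, 6.25 for CG13323, 5.62 for CG14036, 4.66 for CG16713, 4.58 for PGRP-SC2, 4.54 for epsilonTry and 3.64 for betaTry. The fat body transcripts differed by 3.41 for Fbp1, 3.18 for Lsp1alpha, 3.16 for Lsp2 and 2.89 for Lsp1beta. Those lower in ablation differed by -5.92 for 14-3-3zeta RH, -5.08 for CG34278, -3.75 for CG13036, -3.16 for Cib2, -2.93 for CG32318, -2.84 for white, -1.78 for Gr47b, -1.61 for CG12857 and -1.42 for Arc1.

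Midgut digestive enzymes were higher in ablation than in control, with a median log2 change of 4.89 over 14 genes. A lower share of brain tissue would raise markers of other tissues alike. Over members with at least 1 FPKM in some group, tested or not, muscle, haemocyte and salivary gland markers (19, 21 and 12 genes) had medians of 0.03, 0.04 and -0.03. These argue against a rise common to all other tissues, though the tested fat body genes had a median of 0.99. The midgut list (16 genes) lay up to 4.92 above them (bootstrap 95% interval over genes, adjusted over 3 lists, 1.56 to 6.69). That size is no test, since 6 of its genes reached 1 FPKM in control and 1 in activation. Most therefore entered through their ablation values. The 6 were all higher in ablation. Midgut tissue carried along with the ablation brains may account for the pattern: of 21 other midgut genes 6 reached 1 FPKM, and 33.3% of these were at least 2-fold higher in ablation (2 of 6, exact interval 4.33% to 77.7%), too few to decide. The most abundant list members reached 444 FPKM (LysD) and 405 FPKM (Jon65Aiv), while 6 of the 34 list genes reached 1 FPKM in control brains and 4 stand in another list. Carried tissue and a change of the brains by the transgene cannot be told apart for these genes.

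Of 10 fat body markers 7 were lowest in activation and highest in ablation, with a median log2 change of 2.94 over the 10 between these groups, while Obp99a was highest in control (2279 FPKM, with 1333 in activation and 1621 in ablation) and regucalcin and Adgf-A in activation. Over members with at least 1 FPKM in some group, tested or not, the list (12 genes) lay 2.58 above salivary gland markers (0.05 to 5.49). It lay 2.29 above haemocyte markers (0.05 to 3.09) and 1.62 above muscle markers (-0.51 to 2.63), of which 18 of 19 had higher values. Pooled, these markers of other tissues were higher in 35 of 52 genes, with a median of 0.30 (0.07 to 0.65). With lower bounds of 0.05 from a test rewritten after the result, a lower share of brain tissue in ablation stays undecided. Fat body carried along in differing amounts would move all members by a like factor, and their changes had an interquartile range of 2.59 (0.16 to 3.58), so this may hold for the serum proteins but stays undecided. Older larvae in the ablation group would raise ecdysone response genes, which lay at percentile 0.44 of random lists without Fbp1, with 8 genes higher and 18 lower, so this too stays undecided. A lower share of brain tissue, carried fat body, larval age and an effect of the transgenes on fat body genes cannot be told apart. In control brains 10 of the 15 list genes reach 1 FPKM.

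Control differed more from both manipulations than these from each other: the median absolute deviation of log2 changes over genes with a mean of at least 10 FPKM was 0.35 and 0.36 against control and 0.18 between activation and ablation, a ratio of 1.99. Among genes with a mean of at least 100 FPKM the ratio was 1.85 (1.72 to 2.04 over genes), so low values alone do not give it. Shallower control libraries stay undecided, since depth is unknown. In the table of control and activation, 7006 transcripts were at 0 in control and 5673 in activation. In the table of control and ablation the counts were 7003 and 6617, so by zeros ablation stood nearer to control than activation did. A trend with locus length or expression is argued against by 1.99 with the trend removed (1.91 to 2.07), and reads moved between transcripts by 2.06 among genes with 1 transcript (1.97 to 2.16). Larger errors of the control group could give part of it, since simulation from the deposited errors, which exceed the observed spread, gave 1.56 (1.48 to 1.64) where 1.93 was observed, and this and a difference in the brains cannot be told apart. The control cross lacks the yw chromosome and both UAS transgenes, so genetic background stays open and untested.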

How the results depend on the processing

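The tests with a 1.5-fold minimum on gene sums, without other tissues, with overlap at unadjusted p, with arms at q of at most 0.1, and with correlation on gene sums or transcripts above 1 FPKM in all groups were chosen after the data were seen. Of the 18 transcripts called in control against ablation, 0 passed at q of at most 0.01, and 10 passed with normal p-values and 11 with median-centred values, none of them among the 18. In control against activation the count of 0 became 11 at q of at most 0.1, 8 with normal p-values, 11 with median-centred values and 11 with all 3 tables adjusted together, which also took the 18 to 20 and the 46 to 43, with 3 rises lost. Of the 46 called in activation against ablation, 0 passed at q of at most 0.01, while 28 passed with normal p-values (7 of the 46) and 30 with median-centred values (8 of the 46). The statistic that these settings need is missing for the 803, 741 and 863 tested transcripts with a group at 0, and at q of at most 0.01 no transcript can pass with p at 5e-05 unless more reach it. Transcripts called in both manipulations went from 0 to 2 at q of at most 0.1 and to 69 at unadjusted p under 0.05. The cause of the other shifts was not tested.

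With a minimum of 1 FPKM the counts were 18, 0 and 45. The lists outside the random range stayed 8, 5 and 17 in number, except for 16 in activation against ablation with a pseudocount of 5. There mitochondrial respiration was lost (percentile 96.9). In control against ablation that pseudocount lost detoxification (95.2) and salivary gland markers (2.90) and gained neurotransmitter synthesis (99.4) and juvenile hormone (97.9). Of 240 medians of the 20 lists with a result, 236 kept their side of the random range, 1 came outside and 3 came within. This count does not speak to the sign of small medians, which centring on the median can turn. With another pseudocount 7 moved over 1.5-fold: the midgut medians in all 3 comparisons and the immune median in activation against ablation. Of the values of named transcripts 685 moved by at most their deposited standard error and 151 by more or had none, with no call reversed. In the arm test 3R alone passed at q of at most 0.1, with a minimum of 1 FPKM and without the most clustered 5 Mb, the settings run, and q of at most 0.01 leaves no gene to count. No paired analysis was possible because the tables hold no value per replicate, so the replicate block and leaving out each replicate were not run. Unknown depth limits what a value of 0 means.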

Other observations

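All transcripts in this part were chosen after their values were seen, and no hypothesis of its own was tested on them. The larval cuticle genes Lcp1, Lcp2, Lcp3 and Lcp4, secreted proteins of the larval cuticle, had higher group values in control than in either manipulation. Lcp2 had 200.3 FPKM in control and 58.1 FPKM in ablation, and 195 FPKM in control and 22.0 FPKM in activation by the other table. Lcp3 had 254 FPKM in control, 134 FPKM in ablation and 36.0 FPKM in activation. The glial genes Gs2, a glutamine synthetase, and nrv2, a sodium pump subunit, went apart: Gs2 RA had 244 FPKM in control, 271 FPKM in ablation and 92.4 FPKM in activation, and nrv2 RE had 34.5 FPKM, 57.7 FPKM and 111 FPKM. None of these passed at q of at most 0.05 in the authors' deposited table.

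Cyp28d1, a cytochrome P450, rose from 14.7 FPKM in activation to 70.9 FPKM in ablation and passed. Cyp28a5, another P450, had 13.2 FPKM and 41.3 FPKM and did not pass. The sum over transcripts of ImpL2, a secreted insulin binding protein, was 167 FPKM in control and 51.1 FPKM in ablation, and 163 FPKM in control and 71.2 FPKM in activation, with RC lower and RA higher in both manipulations and none passing. The neuropeptide gene Proc, which encodes proctolin, had 73.9 FPKM in activation and 118 FPKM in ablation. Lists within the random range in all 3 comparisons included cell cycle and replication genes, with medians of 0.03, 0.10 and -0.04. Also within it were neuroblast genes with -0.15, -0.16 and -0.07, and neuron markers with 0.24, 0.20 and 0.06.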
